A study of Mus musculus with 3 samples.

How the data were processed

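Epidermis of mouse back skin was profiled by droplet single-cell RNA sequencing (10x Genomics 5' kit, version 2 chemistry) in 3 libraries, each a pool of 3 mice, per the labels. The Gi-DREADD library came from mice with a Dbh-driven Cre and a Cre-dependent inhibitory designer receptor, the control library from mice with the receptor allele and no Cre, and both groups received clozapine N-oxide (CNO) for 3 days. The wild-type library came from untreated mice. For the Gi-DREADD and control mice, the series design describes a mixture at 3:3:2 of cells without CD45, sorted CD8 T cells and sorted non-T immune cells, and a sorted fraction of γδ T cells is not stated to be part of it. It does not name the wild-type mice, so how their cells were sorted or mixed was not taken as known.

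The deposited values are whole-number UMI counts per gene and barcode in filtered matrices. Per the submitters' processing notes, they were made with Cell Ranger 7.2.0 and the genome build GRCm39. The feature lists differed: 33696 genes in the Gi-DREADD and control libraries and 32285 in the wild-type library, of which 31950 were shared by all 3. Gene names were taken from these lists, and no coordinates were used because the reference annotation at hand was of another build. The receptor transgene was not analysed here. Some members of the gene lists are not reported here.

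Barcodes were kept with at least 500 genes and under 10% mitochondrial UMIs, which left out 533, 423 and 286 barcodes of the Gi-DREADD, control and wild-type libraries. Doublets were scored per library against 2 simulated doublets per barcode. The automatic threshold marked 0.0177%, 0.0163% and 0.744% of barcodes, too few to have worked in the Gi-DREADD and control libraries. The highest scores were therefore removed up to an expected rate of 0.8% per 1000 barcodes, which took out 254, 299 and 167 barcodes. This left 4950, 5411 and 4130 cells with medians of 3053, 2902 and 5510.5 UMIs.

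Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 20 nearest neighbours was clustered with the Leiden method at resolution 1.0. A cluster was named from markers fixed in advance when at least 3 and at least 50% of a type's markers were 2-fold above the other cells and detected in 10% of its cells. It stayed unnamed where markers of another type outnumbered its own among its top 10 genes. Clusters with CD3 gene detection of at least 40% were pooled as T lineage and clustered again (1500 genes, 20 components, 15 neighbours, resolution 2.0). CD8 T-like subclusters had Cd8a and Cd8b1 in at least 30% of cells and Cd8a at least 5 times as often as Cd4, and γδ T-like subclusters had Trdc in at least 50%. These naming thresholds, the doublet rate and the second clustering were chosen after the data were seen.

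UMIs were summed over the cells of a class in each library and divided by the class total to give CPM. Each CPM carries an exact 95% Poisson interval, each ratio of CPM an exact conditional binomial interval, and each share of cells an exact Clopper-Pearson interval. All intervals cover counting error only. Cells are not replicates and each group had 1 library, so no test was run and no p-value is given. A gene was measured in a class with at least 20 UMIs over both libraries. For each of 31 gene lists, the median log2 ratio of the measured members (pseudocount 0.5 UMI, at least 3 members) was given with an interval from 2000 Poisson draws of the counts and its percentile among 10000 random lists of the same size, matched on mean expression within a window of 50 genes. Random members were drawn one by one. The percentile therefore does not allow for members that vary together, as markers of a cell type do when the mixture of cells differs. In the text, a gene "rose" or "fell" where the interval of its ratio excluded 1.

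Named genes followed a rule fixed before the data were examined, as were the lists, the comparisons and most alternatives. Among genes with at least 50 UMIs whose Gi-DREADD CPM lay outside the range of control and wild type, those with the interval farthest from 1 were taken: 10 per direction in CD8 T-like cells and keratinocytes and 3 in each non-T immune class. Mitochondrial, ribosomal, predicted, haemoglobin, receptor segment and sex-linked genes were left out, as were genes at least 10 times higher in another class (2 in CD8 T-like cells, 45 in keratinocytes, 93 in macrophage-like cells and 12 in cluster 2). The wild-type condition rests on 2 cells in CD8 T-like cells. Without it, 10 of the 10 higher but 1 of the 10 lower names were shared in CD8 T-like cells, and 4 of the 10 higher and 7 of the 10 lower in keratinocytes. Between Gi-DREADD and control, non-T immune types and basal and suprabasal keratinocytes on their own were compared with at least 200 cells in both libraries. Control and wild type were compared in the same classes with no such minimum for the wild type, which had 71 macrophage-like cells. Basal and suprabasal keratinocytes were therefore not compared on their own, and gene values of Langerhans, CD4 T-like and γδ T-like cells appear only in the closing section. Cluster 2 was compared by number, a choice made after the data were seen.

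On counts simulated from these libraries, the intervals recovered 82.0%, 84.0% and 98.0% of genes changed 2-fold in CD8 T-like cells (1676 genes), keratinocytes (8231 genes) and macrophage-like cells (10593 genes). They recovered 100.0% of genes changed 4-fold in each. For unchanged genes the interval held the true ratio in 96.6%, 96.0% and 96.0% of cases. These rates speak to counting error only, which is the error that the intervals assume. They do not show how the intervals fare where the UMIs of a gene gather in few cells, or how mice differ. For Krt36 in keratinocytes, 1173 of 1311 Gi-DREADD UMIs lay in the cell richest in it.

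Alternatives covered the cell filter, doublets, clustering resolution, scaling by the median ratio, the mean of each cell's CPM, averaging within clusters, thinning each cell to 1000 UMIs, the wild type as reference and the UMI minimum (100 or 5). Thinned medians are those of 20 random draws, because single draws gave values of opposite sign. Thinned shares of cells with a UMI come from a single draw. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.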

Results

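Single cells from the epidermis of mouse back skin were sequenced in 3 libraries to describe CD8 T cells and epidermal cells after sympathetic neurons had been silenced. In the Gi-DREADD library, Cre driven by Dbh, the gene for the enzyme that makes noradrenaline, switched on an inhibitory receptor activated by CNO. The control mice received CNO without Cre, and the wild-type mice were untreated. The Gi-DREADD library held 22437644 UMIs in 5733 barcodes, the control library 22632580 UMIs in 6133 barcodes and the wild-type library 36127487 UMIs in 4583 barcodes. After filtering, 4950, 5411 and 4130 cells remained, with median mitochondrial shares of 1.76%, 1.25% and 0.675% of UMIs. Each group was 1 pool of 3 mice, so there were no replicates, and no difference could be set against the spread between mice.

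Non-T immune cells made up 85.9% of Gi-DREADD cells (95% interval 84.9 to 86.9), 87.7% of control cells (86.8 to 88.6) and 34.5% of wild-type cells (33.0 to 36.0). T lineage cells made up 7.05%, 9.63% and 17.6%, and CD45-negative-like cells 7.05%, 2.68% and 48.0%, in the same order. In the Gi-DREADD and control libraries these shares lay far from the stated 3:3:2 mixture, and CD8 T-like cells were 0.747% and 1.44% of cells. Sorting, mixing and recovery can set such shares, so they were not compared between groups. Within the CD45-negative-like cells, 256, 59 and 1399 were keratinocyte-like. T lineage cells held 37, 78 and 2 CD8 T-like cells, and 24.6%, 40.1% and 47.9% of them stayed unnamed. Langerhans-like cells, the antigen-presenting cells of the epidermis, formed 2.49% (2.05 to 3.01) of Gi-DREADD non-T immune cells, 2.87% (2.41 to 3.38) of control and 5.76% (4.61 to 7.10) of wild-type ones. The Gi-DREADD and control intervals overlapped.

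**Figure D1:**
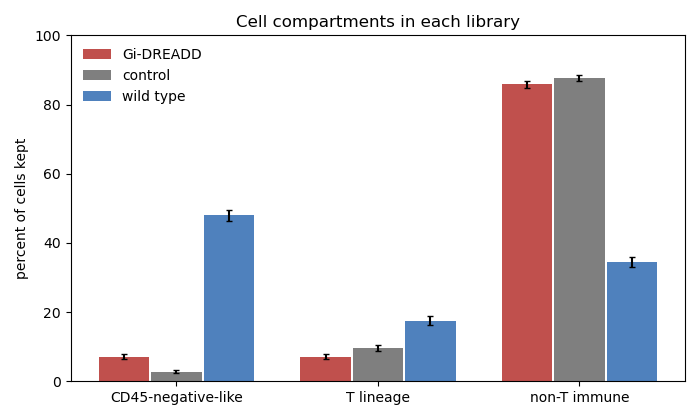
Percent of cells kept (y axis) that were CD45-negative-like, T lineage or non-T immune (x axis) in the Gi-DREADD, control and wild-type libraries, with 95% exact binomial intervals as error bars. Non-T immune cells were 85.9% and 87.7% of the Gi-DREADD and control libraries and 34.5% of the wild-type library.

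The first comparison asked how CD8 T cells differed when sympathetic neurons were silenced. In the 37 Gi-DREADD and 78 control CD8 T-like cells (188177 and 329555 UMIs), genes of the cAMP response were higher in the Gi-DREADD library. Their median log2 ratio was 0.32 (0.13 to 0.48) over 15 measured members, at percentile 99.7 of the matched random lists, and 7 members rose while 0 fell. The nuclear receptor genes Nr4a1 (CPM ratio 1.66, 1.40 to 1.97), Nr4a2 (1.43, 1.17 to 1.75) and Nr4a3 (1.38, 1.17 to 1.62), which are also early targets of T cell receptor signals, rose with the transcription factor gene Crem (1.46, 1.13 to 1.88). Genes of cytotoxicity and effector cytokines were lower, with a median of −0.29 (−0.60 to −0.03) over 14 members at percentile 0.66. Of these, 5 fell, among them the cytolytic protease gene Gzmb (0.314, 0.119 to 0.711) and the chemokine gene Ccl4 (0.314, 0.207 to 0.462), and the T cell growth factor gene Il2 rose (2.67, 1.49 to 4.87). Ccl4, like the list members Tnf and Ccl3, was higher in control macrophage-like than in control CD8 T-like cells, so its fall may not be one of T cells. UMIs of 6 macrophage genes were present in 21.6% of Gi-DREADD and 53.8% of control CD8 T-like cells, and in cells without them the cytotoxicity median was 0.055. It was −0.028 over members with at least 100 UMIs and −0.0702 after thinning, and with CD8 T cells taken by their own Cd8a or Cd8b1 UMI instead of by cluster (70 and 153 cells) the cAMP response median was 0.075.

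Tissue residency genes had a median of −0.08 (−0.29 to 0.10) at percentile 17.3, with 2 of 15 members higher and 3 lower. Itgae (0.752, 0.570 to 0.984), the CD103 integrin chain that binds epithelial E-cadherin, Itga1 (0.509, 0.272 to 0.902), a collagen-binding integrin chain, and the chemokine receptor gene Cxcr6 (0.724, 0.536 to 0.969) fell. Xcl1, a chemokine that attracts dendritic cells, rose (2.33, 1.93 to 2.82), with 113 of its 262 Gi-DREADD UMIs in 1 cell, and Cd101 rose (1.71, 1.08 to 2.69). At 1000 UMIs per cell, Itgae was detected in 32.4% (18.01 to 49.8) of Gi-DREADD and 38.2% (27.2 to 50.0) of control CD8 T-like cells, and Cxcr6 in 21.6% (9.83 to 38.2) and 42.1% (30.9 to 54.0). All thinned shares here come from a single random draw, and their intervals do not cover the spread between draws. The intervals of the 2 libraries overlapped for both genes, which by itself does not decide whether the shares differed. In keratinocytes, taken as a class that should lack both genes, the thinned shares were 0.781% and 1.72% for Itgae and 0 of 256 and 0 of 58 cells for Cxcr6. With all UMIs, at median depths of 4859 and 4070 UMIs in CD8 T-like cells and 10839.5 and 9329 in keratinocytes, Itgae reached 86.5% and 82.1% of CD8 T-like cells and Cxcr6 73.0% and 69.2%. The unthinned keratinocyte shares were 1.95% and 1.69% for Itgae and 1.17% and 0 of 59 cells for Cxcr6. No order was read from the unthinned shares, which ran against the CPM. Among recirculation genes (median −0.09, −0.74 to 0.24), Klf2, which maintains the exit receptors of circulating T cells, fell (0.170, 0.0661 to 0.369), as did Ly6c2 (0.408, 0.258 to 0.624), and the list median was −0.74 in cells without a macrophage UMI.

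T cell receptor signalling genes had a median of 0.13 (−0.08 to 0.43), with 4 of 13 members higher, Icos among them (1.45, 1.24 to 1.70), and Cd3e lower (0.775, 0.609 to 0.980), and the median was 0.46 over members with at least 100 UMIs. TGF-beta receptors and targets had a median of 0.08 (−0.26 to 0.29) over 11 members and MHC class I genes one of −0.07 (−0.18 to 0.14) over 11, and 0 members of either list rose or fell. The medians were −0.29 (−0.74 to 0.25) for inhibitory receptors, 0.07 (−0.90 to 0.54) for interferon-stimulated genes, −0.05 (−0.20 to 0.26) for NF-kB and inflammation and −0.36 (−0.71 to 0.06) for the glucocorticoid response. They were −0.09 (−0.36 to 0.19) for glycolysis and hypoxia, 0.09 (−0.29 to 0.60) for the cell cycle, −0.53 (−1.16 to 0.66) for lipid uptake and synthesis and −0.03 (−0.25 to 0.19) for dissociation stress. A cycling T lineage subcluster, with Mki67 in 100% of its cells, Cd8a in 42.1% and Cd4 in 31.6%, stayed unnamed. Its 13 Gi-DREADD and 32 control cells lay outside the CD8 T-like class. The cell cycle median was −0.51 with doublets kept, −0.62 at clustering resolution 2.0, −0.39 with CD8 T cells taken by their own UMI and −0.53 in cells without a macrophage UMI. That of the glucocorticoid response was 0.15 in the last cells and 0.073 after thinning, and that of interferon-stimulated genes 0.54 over members with at least 5 UMIs. Type 17, adrenergic receptor, γδ T, keratinocyte and haemoglobin genes had fewer than 3 measured members.

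By the fixed rule, the genes highest in Gi-DREADD CD8 T-like cells were Xcl1, Arhgef3 (2.69, 1.79 to 4.09), Itgav (2.71, 1.71 to 4.33), Cdk8 (1.85, 1.63 to 2.10), Ext1, Kcnq5, Il2, Filip1l, Gfod1 and Cdkn1a. Itgav encodes the alpha chain of integrins that activate latent TGF-beta, and Cdkn1a the cell cycle inhibitor p21. The ratios of Ext1, Kcnq5, Filip1l, Gfod1 and Cdkn1a lay between 1.86 and 2.86. The genes lowest by the rule were Bzw2 (0.384, 0.164 to 0.803), Glrx (0.429, 0.208 to 0.818), H3f3b (0.746, 0.668 to 0.832), B4galt1, Taf1d, Ranbp9, Lpxn, Romo1, Hp1bp3 and Ldha. Ldha, the lactate dehydrogenase of glycolysis, stood at 0.635 (0.456 to 0.872). Only Bzw2 of these 10 was also chosen without the wild-type condition, which rests on 2 cells, so the lower names depended on it. At 1000 UMIs per cell the log2 ratio was 0.71 for Xcl1 and −0.42 for Glrx, against 1.22 and −1.18 with all UMIs. With CD8 T cells taken by their own Cd8a or Cd8b1 UMI, the log2 ratio of Ext1 changed sign (−0.063, against 1.42), and it was 0.24 for Itgav, 0.15 for Kcnq5, 0.021 for Cdkn1a, 0.51 for Gfod1, 0.62 for Xcl1, −0.076 for H3f3b and −0.021 for Romo1.

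Mitochondrially encoded genes, a sign of RNA quality, had a median of 0.33 (0.21 to 0.41) in the same cells, and 0.060 in those without a UMI of the 6 macrophage genes. Genes of Langerhans cells had one of −1.64 (−2.96 to −0.46) over 3 members, or −4.04 with CD8 T cells taken by their own UMI.

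In keratinocytes (256 Gi-DREADD and 59 control cells, 3303953 and 672595 UMIs), the question was how the epidermal cells themselves differed. Suprabasal differentiation genes were lower in the Gi-DREADD library and basal genes higher. The suprabasal median was −0.80 (−0.91 to −0.53) over 15 members, at percentile 0.00, with 9 members lower and 2 higher. The keratin pair of differentiating layers fell, Krt1 to a ratio of 0.332 (0.303 to 0.364) and Krt10 to 0.324 (0.312 to 0.337), as did Krtdap (0.563, 0.544 to 0.582) and Sbsn (0.455, 0.429 to 0.482). Flg (4.12, 1.55 to 15.5) and Klk7 (4.75, 2.79 to 8.79), which act in the outer layers, rose. The suprabasal-like cluster was the largest in both libraries (102 and 31 cells). It formed 39.8% (33.8 to 46.1) of Gi-DREADD and 52.5% (39.1 to 65.7) of control keratinocytes, and these intervals overlapped. At clustering resolution 2.0 suprabasal-like cells were 7.93% and 23.8%, so their share depended on the clustering. At an equal mixture of the main keratinocyte clusters the suprabasal median was −0.46 (−0.65 to −0.25). At clustering resolution 2.0 an equal mixture, which could be made for 181 Gi-DREADD and 48 control cells, gave 0.18, with an interval that included 0 (−0.04 to 0.38), and with each cell weighted equally the median was −0.47. The basal median was 0.54 (0.43 to 0.62), above all 10000 matched random lists, and 11 of 14 members rose, including the keratin gene Krt5 (1.73, 1.66 to 1.81), the hemidesmosome integrin Itga6 (1.78, 1.51 to 2.10) and the laminin chain Lamb3 (1.95, 1.42 to 2.74).

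Genes of signals that keratinocytes can send to T cells went both ways. In this class, 195 of 256 Gi-DREADD and 32 of 59 control cells held no UMI of Lyz2, Tyrobp, Fcer1g, Cd207, C1qa or Ptprc. Whether myeloid RNA in the other cells contributed to the values of this paragraph was not tested. T cell survival and attraction genes had a median of −0.24 (−0.46 to 0.13) over 12 members at percentile 13.1. Il15, a survival cytokine of memory CD8 T cells, fell (0.254, 0.111 to 0.595) with its presenting receptor Il15ra (0.444, 0.263 to 0.773), Cxcl10 (0.467, 0.284 to 0.788) and Cxcl14 (0.856, 0.795 to 0.923). Ccl27a, the keratinocyte chemokine for skin-homing T cells, rose (2.17, 1.96 to 2.41). TGF-beta ligands and activators had a median of 0.11 (−0.19 to 0.33) over 10 members at percentile 91.5. Tgfb1 (0.522, 0.343 to 0.811) and Itgb6 (0.586, 0.367 to 0.965), a chain of the integrin that activates TGF-beta in epithelium, fell with Ltbp2 (0.557, 0.324 to 0.998), while Ltbp1 (2.24, 1.17 to 4.80) and Ltbp4 (1.47, 1.04 to 2.14) rose. TGF-beta receptors and targets had a median of −0.30 (−0.41 to 0.07), with 3 of 14 members lower and 2 higher. The survival and attraction median was −0.62 with each cell weighted equally and −0.46 at an equal cluster mixture at resolution 2.0. That of TGF-beta ligands and activators ran from −0.24 at clustering resolution 2.0 to 0.59 at 0.5. Adrenergic receptor genes had fewer than 3 measured members.

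Genes of lipid uptake and synthesis were lower, with a median of −0.95 (−1.08 to −0.52) over 13 members. Of these 9 fell, such as the fatty acid binding protein gene Fabp5 (0.491, 0.437 to 0.552) and the desaturase gene Scd1 (0.239, 0.186 to 0.306). The lipid median was −0.37 with the looser cell filter, −0.29 with doublets kept, −0.37 at clustering resolution 0.5 and −0.49 without the cell richest in each gene. At an equal cluster mixture at resolution 2.0 it was −0.0082, and against wild type −0.077. Axon guidance and neurotrophic factor genes had a median of 0.55 (0.24 to 0.85) over 12 members, of which 3 rose, 1 fell and 8 lay within counting error. The semaphorin genes Sema3c (1.72, 1.33 to 2.25) and Sema3e (2.39, 1.58 to 3.80) and the ephrin gene Efnb1 (1.45, 1.08 to 2.00) rose.

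Stress keratins and alarmins had a median of 0.60 (0.46 to 0.74) over 8 members, 1 of them with 0 control UMIs. Krt17 (9.27, 7.89 to 10.96) and Krt6a (6.16, 4.51 to 8.62), keratins of the hair follicle and of wounded epidermis, rose, and the EGF receptor ligand genes Areg (0.219, 0.154 to 0.311) and Hbegf (0.652, 0.546 to 0.784) fell. In the Gi-DREADD library 1326 of 6874 Krt17 and 481 of 1240 Krt6a UMIs lay in 1 cell. Follicle or isthmus cells, for which Krt17 was a naming marker, formed 29.7% (24.2 to 35.7) of Gi-DREADD and 18.6% (9.69 to 30.9) of control keratinocytes. Cell cycle genes had a median of 0.93 (0.75 to 1.85) over 18 members, or 0.91 with members at 0 control UMIs set to the floor of 3 counts. Of these 11 rose, such as Mki67 (1.99, 1.12 to 3.84) and Hmgb2 (1.68, 1.40 to 2.03). A cluster led by cell cycle genes (cluster 19, with 27, 24 and 74 cells in the Gi-DREADD, control and wild-type libraries) stayed outside the class. The stress keratin median was −0.54 at clustering resolution 0.5, −2.73 against wild type (−1.97 with 0 UMIs at the floor), 0.066 over members with at least 5 UMIs, 1.38 without the richest cell and 1.12 at an equal cluster mixture at resolution 2.0. The cell cycle median was −0.039 at clustering resolution 2.0.

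MHC class II genes had a median of −2.56 (−2.74 to −2.27) and Langerhans cell genes one of −2.50 (−2.71 to −2.06) in these keratinocytes, and 73.1% (69.7 to 76.4) of the control class II UMIs lay in 3 cells. At an equal cluster mixture at resolution 2.0 the medians of these lists were −3.44 and −3.35. The median of mitochondrially encoded genes was 0.21 (0.16 to 0.25), but −0.11 after thinning, with 18 of 20 draws below 0, and −0.11 with each cell weighted equally. The other medians were 0.14 (−0.11 to 0.30) for follicle stem cell and germ genes, 0.13 (0.02 to 0.29) for glycolysis and hypoxia, 0.11 (−0.12 to 0.23) for the cAMP response and 0.04 (−0.04 to 0.23) for MHC class I. They were 0.03 (−0.44 to 1.11) for interferon-stimulated genes, −0.18 (−0.27 to 0.09) for NF-kB and inflammation, −0.0043 (−0.11 to 0.16) for the glucocorticoid response and −0.03 (−0.09 to 0.03) for dissociation stress. Without the richest cell the median was 0.31 for follicle genes, 0.43 for glycolysis, 0.33 for the cAMP response, 0.27 for MHC class I, 0.15 for NF-kB, 0.20 for the glucocorticoid response and 0.21 for dissociation stress. After thinning it was −0.20 for the cAMP response, 0.35 for MHC class I, −0.50 for NF-kB and −0.14 for the glucocorticoid response, and at an equal cluster mixture at resolution 2.0 that of MHC class I was 0.64. Among haemoglobin genes Hba-a1 alone was measured (13 and 17 UMIs).

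The largest differences by the fixed rule often rested on single cells. Krt36, a hair keratin, stood at a ratio of 26.7 (14.5 to 55.8) with 1173 of 1311 Gi-DREADD UMIs in 1 cell. S100a3 (3.45, 2.27 to 5.51) had 374 of 390 in 1 cell, and without the richest cell in each library its log2 ratio turned to −1.50. Krt2 (2.40, 2.05 to 2.82) had 916 of 1990 Gi-DREADD and 154 of 169 control UMIs in 1 cell, and without these its log2 ratio was 3.82, against 1.26. Broader were Cald1, an actin-binding protein gene (5.87, 3.32 to 11.5; 60 cells), and Sema5a (3.24, 1.96 to 5.76; 97 cells). Fbxo32, Stfa1, Gpx2 and Col23a1 lay between 3.30 and 5.39. At 1000 UMIs per cell the log2 ratio was 0.41 for Fbxo32, 0.67 for Stfa1, 0.36 for Gpx2 and 0.45 for S100a3, against 1.74, 2.27, 2.00 and 1.76 with all UMIs, and 5, 8, 4 and 5 of 20 draws lay below 0. With the same step, Krt36 went from 4.67 to 2.61, Krt6a from 2.61 to 1.36 and Hpgds from −3.00 to −1.82. The cornified envelope gene Lor was 53.4-fold lower (35.1 to 84.9), with 250 of 261 control UMIs in 1 cell, and Lce1m was 109-fold lower, with 190 of 199 in 1 cell. Sptlc3, a subunit of the enzyme that starts ceramide synthesis, was 4.48-fold lower (3.58 to 5.60) and was detected in 53 Gi-DREADD and 17 control cells. The remaining genes lowest by the rule were Crct1, Ereg, Hpgds, Skint5, Krt77, Arhgef10l and Krt78, from 35.4-fold for Crct1 to 4.43-fold for Krt77. For Crct1, 66 of 72 control UMIs lay in 1 cell. For Skint5 and Arhgef10l the Gi-DREADD CPM was 0.974 and 0.957 of the wild-type CPM, and the control CPM was 4.82 and 4.97 times it. For the others of these 7 genes the Gi-DREADD CPM was 0.00952 to 0.393 of the wild-type CPM. At an equal cluster mixture at resolution 2.0 the log2 ratio was −1.08 for Sptlc3, −0.69 for Krt77, −0.68 for Krt78 and −0.70 for Skint5, against −2.16, −2.15, −2.28 and −2.31. Without the richest cell, that of Lor was −1.53, against −5.71.

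**Figure D2:**
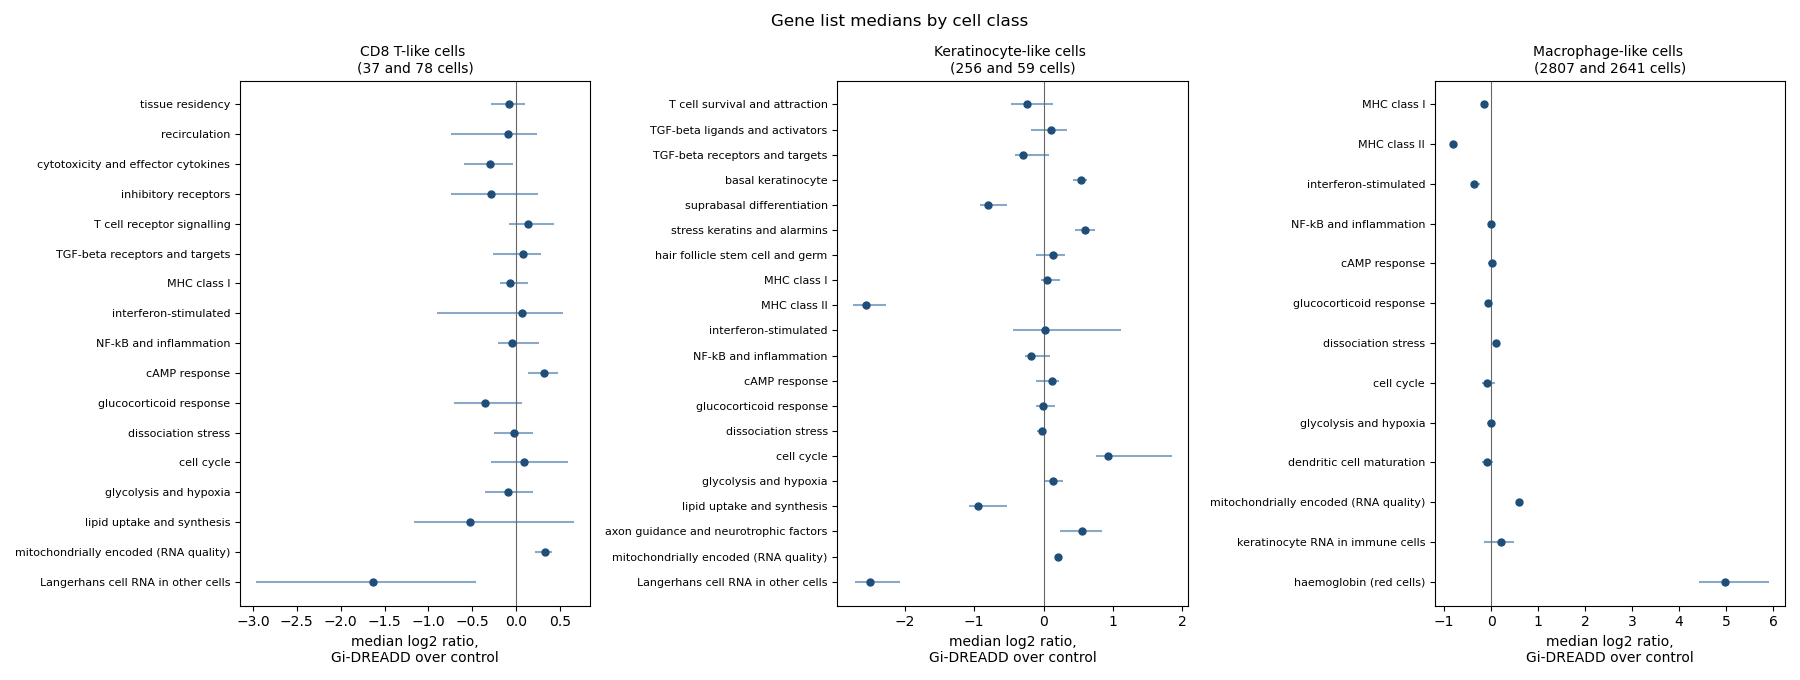
Median log2 ratio of CPM, Gi-DREADD over control (x axis), for each gene list with at least 3 measured members (y axis) in CD8 T-like, keratinocyte-like and macrophage-like cells. Points are medians and lines 95% counting intervals; the suprabasal median in keratinocytes lies at −0.80 and the MHC class II median in macrophage-like cells at −0.82.

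Macrophage-like cells were the most numerous non-T immune class, with 2807 Gi-DREADD and 2641 control cells (10171754 and 9652434 UMIs). MHC class II genes, which present antigen to CD4 T cells, were lower in the Gi-DREADD library: the median was −0.82 (−0.86 to −0.78), at percentile 0.00, and 7 of 7 members fell. H2-Aa stood at 0.596 (0.582 to 0.610), Cd74, the invariant chain, at 0.549 (0.541 to 0.558) and Ciita, the master regulator of the class II genes, at 0.365 (0.264 to 0.499). Whether RNA of other antigen-presenting cells contributed to these class II values was not tested. Interferon-stimulated genes were lower too, with a median of −0.37 (−0.44 to −0.24) over 22 members at percentile 0.00. Of these 12 fell, among them Isg15 (0.764, 0.707 to 0.824) and the nucleic acid sensor Zbp1 (0.530, 0.408 to 0.686), and Rsad2 rose (1.28, 1.17 to 1.40).

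NF-kB and inflammation genes had a median of 0.0037 (−0.02 to 0.07) at percentile 54.8, with 6 of 17 members higher and 5 lower. The monocyte chemokine gene Ccl2 rose (1.32, 1.29 to 1.34) and Il6 fell (0.761, 0.681 to 0.850). MHC class I genes had a median of −0.16 (−0.21 to −0.11) and dissociation stress genes one of 0.10 (0.06 to 0.12), or 0.023 averaged within clusters. Hspa1b, a heat shock gene, rose 2.00-fold (1.90 to 2.12) and Fos fell (0.825, 0.812 to 0.840). The medians were 0.025 (−0.06 to 0.09) for the cAMP response, −0.07 (−0.13 to −0.02) for the glucocorticoid response, −0.08 (−0.20 to 0.08) for the cell cycle, 0.0034 (−0.10 to 0.04) for glycolysis and hypoxia and −0.09 (−0.19 to 0.04) for dendritic cell maturation. Among adrenergic receptors, Adrb1 stood at 0.356 (0.114 to 0.957) with 6 and 16 UMIs.

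Genes highest by the fixed rule were Col13a1, a transmembrane collagen (13.7, 9.43 to 20.5; 296 and 30 cells with a UMI), Adgra1 (60 and 2 UMIs) and Gtsf2 (11.2, 7.09 to 18.7). The lowest were AA467197, 13.2-fold lower (6.93 to 28.1), Dcstamp, which drives macrophage fusion, 6.13-fold lower (3.21 to 12.9), and Sirpb1b, 5.65-fold lower (2.94 to 11.9). Mitochondrially encoded genes had a median of 0.60 (0.58 to 0.62) in these cells and keratinocyte genes one of 0.21 (−0.15 to 0.48). The haemoglobin median was 4.98 (4.42 to 5.92), with 337 of the 339 Gi-DREADD UMIs of Hba-a1 in 1 cell, and its direction depended on the doublet step, since it was −0.62 with doublets kept, and averaged within clusters it was 2.00.

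Cluster 1 held more Gi-DREADD macrophage-like cells (1331) than the other clusters and cluster 0 more control ones (1207), and averaged within clusters the MHC class II median was −0.51. With each cell weighted equally the interferon median was −0.19, and at clustering resolution 0.5 the log2 ratio of Dcstamp was 0.67. At 1000 UMIs per cell it was −1.49, against −2.56 with all UMIs. Averaged within clusters, the log2 ratio was −1.44 for AA467197, −0.81 for Dcstamp and −1.13 for Sirpb1b, against −3.65, −2.56 and −2.45.

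Cluster 2, led by Ccl8, Cd209d and interferon-induced genes, carried macrophage markers but stayed unnamed. It formed 11.2%, 11.02% and 36.2% of Gi-DREADD, control and wild-type non-T immune cells, while the unnamed clusters 3, 5 and 10 formed 13.2%, 15.2% and 0.632%, 4.49%, 9.69% and 25.7%, and 1.60%, 4.70% and 8.15%. In cluster 2 (477 and 523 cells), NF-kB and inflammation genes were higher, with a median of 0.22 (0.10 to 0.33) at percentile 99.4 and 7 of 15 members higher. Nfkbia (1.34, 1.25 to 1.44), the NF-kB inhibitor, Ccl2 (1.35, 1.27 to 1.45) and Csf3 (8.28, 2.88 to 32.6) rose, and Relb fell (0.759, 0.594 to 0.966). The median was 0.20 (0.01 to 0.26) for the cAMP response, −0.07 (−0.13 to −0.02) for MHC class II, −0.01 (−0.15 to 0.17) for interferon-stimulated genes and −0.11 (−0.17 to 0.06) for MHC class I. It was 0.53 (0.47 to 0.60) for mitochondrially encoded genes. By the fixed rule Col13a1 (15.02, 5.51 to 57.3), the sodium channel gene Scn3a and the kinase gene Sgk3 (4.46, 3.59 to 5.58) were highest. Retnla, a marker of alternatively activated macrophages, was 3.39-fold lower (3.04 to 3.80), with Pphln1 and Pias2 3.13-fold and 3.26-fold lower. The NF-kB median was −0.016 at clustering resolution 2.0 and 0.096 with each cell weighted equally.

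The last comparison set the control library against the wild-type library, neither with silenced neurons, to show how far such libraries lay apart. In keratinocytes, stress keratins and alarmins were lower in control (median −2.22, −2.79 to −2.06, 10 of 12 members lower). With members at 0 UMIs set to the floor of 3 counts, their median was −1.62. Also lower were cAMP response genes (−0.97, −1.18 to −0.74), MHC class I genes (−0.76, −1.01 to −0.65) and dissociation stress genes (−0.73, −0.87 to −0.61). MHC class II genes were higher (3.02, 2.77 to 3.17) with Langerhans cell genes (3.02, 2.75 to 3.17), as were lipid genes (0.87, 0.40 to 1.17) and mitochondrially encoded genes (1.37, 1.29 to 1.44). T cell survival and attraction genes had a median of −0.31 (−0.95 to −0.06), or −0.59 at that floor, and suprabasal genes one of −0.05 (−0.37 to 0.03). Basal-like clusters held most wild-type keratinocytes (746 of 1399), and 333 of these lay in a cluster that was nearly all wild type.

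In macrophage-like cells, of which the wild-type library held 71, mostly in cluster 4 (48 cells), MHC class II (−1.82, −1.89 to −1.75) and interferon-stimulated genes (−0.97, −1.39 to −0.82) were lower in control and cAMP response genes higher (0.94, 0.57 to 1.18). In cluster 2 the medians were 0.52 (0.45 to 0.62) for MHC class II, 0.51 (0.31 to 0.77) for interferon-stimulated, 0.62 (0.38 to 0.78) for cAMP response and 0.75 (0.68 to 0.81) for mitochondrially encoded genes. Wild type and control differed in CNO, genotype, the set of genes counted and depth (medians of 5510.5 and 2902 UMIs over all cells kept). How the wild-type cells were sorted or mixed was not known, so the distance between these libraries may reflect that as well. The control library was shared with the comparisons above. The 2 wild-type CD8 T-like cells allowed no comparison. A further 46 wild-type T lineage cells were found by a Cd8a or Cd8b1 UMI and none of Cd4 or Trdc, of which 1 fell in the CD8 T-like class. So the small class does not show that the wild-type library lacked CD8 T cells, and these cells were not compared.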

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

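The tests on cytotoxicity genes and on suprabasal genes below were chosen only after those results had been seen. The tests on MHC class II genes in keratinocytes were written before theirs. Those on cytotoxicity genes replaced earlier ones: a median over the 6 macrophage genes, of which 1 was measured, their CPM ratio, and the unthinned median over the 7 members measured after thinning (−0.17, −0.35 to 0.03).

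Dbh, the gene of the Cre driver, was not part of the main comparisons and lay above the control level in the Gi-DREADD library. It stood at a CPM of 1.28 (0.837 to 1.88) over all Gi-DREADD cells, with 26 UMIs in 24 cells, against 0.0984 (0.0119 to 0.355) in control with 2 UMIs and 1 UMI in wild type. Of the Gi-DREADD barcodes, 1.53% (1.23 to 1.89) had at least 20% mitochondrial UMIs, against 0.228% (0.125 to 0.383) of control and 0.0655% of wild-type barcodes. These barcodes were filtered out. γδ T-like cells made up 25.8% (21.3 to 30.7) of Gi-DREADD T lineage cells, 7.87% (5.71 to 10.5) of control and 37.1% (33.6 to 40.7) of wild-type ones. The mixture stated for the Gi-DREADD and control mice did not name γδ T cells, and sorting and mixing can set this share, so it is given as a value and not as a difference between groups.

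Cytotoxicity and effector cytokine genes were lower in Gi-DREADD CD8 T-like cells (median −0.29), as were 6 macrophage genes together (CPM ratio 0.173, 0.0722 to 0.357; 8 and 81 UMIs). Macrophage RNA dilutes transcripts that macrophages lack. Its share (0.194% and 1.06% of UMIs) was taken off with the mean profile of the macrophage-like cells of each library. The median was then −0.30 (−0.61 to −0.049). Shares this small could hardly move the median by dilution. The step therefore shows only that RNA of the mean profile, at these shares, did not account for the fall. The 11 members lower in control macrophage-like than in control CD8 T-like cells had a median of −0.17. Its interval included 0 (−0.32 to 0.17). In the 29 and 36 cells without UMIs of the 6 genes the median was 0.055 (−0.42 to 0.20), an interval too wide to decide whether T cells that held them were in another state. Depth stayed open as well, since after thinning the median was −0.0702 with draws from −0.52 to 0.15. Thinning also left fewer members measured, and the unthinned median over 7 still measured in a single draw was −0.17 (−0.35 to 0.03). The step therefore cannot separate depth from the change of members. Silencing of sympathetic neurons, which the design names, stayed open and untested.

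Suprabasal differentiation genes were lower in Gi-DREADD keratinocytes (median −0.80). Another mixture of keratinocyte clusters is a candidate explanation that stayed open: with the same mixture in both libraries the median was −0.46 (−0.65 to −0.25), but 0.18 (−0.04 to 0.38) with finer clusters, of which 3 of 7 had enough cells. Without the cell richest in each gene it was −0.72 (−0.79 to −0.50). This argues against a single rich cell per gene as the whole cause. The step took out only that cell in each library, so it cannot speak to a few rich cells. Differences among the 3 pooled mice of a library and the silencing itself stayed open, because 1 library per group cannot separate them.

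MHC class II genes were lower in Gi-DREADD keratinocytes (median −2.56). Myeloid cells or their RNA in keratinocyte droplets are a candidate explanation, because in cells without a myeloid UMI 25 of the 689 control class II UMIs were left (111 of 555 in Gi-DREADD) and the CPM ratio was 0.837 (0.538 to 1.35). The small number of control cells bears on it too, since 73.1% (69.7 to 76.4) of the control class II UMIs lay in 3 cells. Silencing of the neurons stayed open and untested here too.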

How the results depend on the processing

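Alternatives without the macrophage UMI, with CD8 T cells taken by their own UMIs, without the cell richest in a gene and with the same cluster mixture at both resolutions, and the use of 20 thinning draws, were tests chosen only after results had been seen. Of 1385 values recomputed, 1145 stayed within their counting interval, 221 moved beyond it, and 19 reversed a direction that their interval had called. Of all values, 110 changed sign, which counts those with an interval that included 0. The cause was not tested for any of them, except that other clusterings changed which cells formed a class and that a single cell held most UMIs of S100a3.

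At the main resolution, suprabasal-like cells were 39.8% of Gi-DREADD, 52.5% of control and 20.4% of wild-type keratinocytes. At resolution 0.5, they were 56.7% of Gi-DREADD and 27.7% of wild-type keratinocytes. TGF-beta ligands and activators in keratinocytes gave 0.59, stress keratins −0.54 and Dcstamp in macrophage-like cells 0.67. At resolution 2.0, suprabasal-like cells were 7.93%, 23.8% and 16.2% of Gi-DREADD, control and wild-type keratinocytes. TGF-beta ligands gave −0.24, the cell cycle in keratinocytes −0.039 and NF-kB genes in cluster 2 −0.016. TGF-beta ligands gave 0.41 with the looser cell filter, 0.41 with doublets kept, 0.43 over members with at least 100 UMIs and 0.38 without the richest cell. With doublets kept, haemoglobin genes in macrophage-like cells gave −0.62. At 100 UMIs, suprabasal genes gave −0.96 and cytotoxicity −0.028.

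With the mean of each cell's CPM, T cell survival and attraction genes gave −0.62, suprabasal genes −0.47, interferon-stimulated genes in macrophage-like cells −0.19, NF-kB genes there 0.073 and mitochondrially encoded genes in keratinocytes −0.11, the last also −0.11 after thinning. The CD8 definition by UMI gave −0.063 for Ext1, cells without a macrophage UMI 0.055 for cytotoxicity, the same cluster mixture −0.46 for suprabasal genes (at resolution 2.0, over fewer cells, 0.18, with −0.46 for T cell survival and attraction) and removal of the richest cell −1.50 for S100a3.

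Against wild type, keratinocytes gave −0.56 for T cell survival and attraction, 0.71 for TGF-beta ligands, −1.07 for suprabasal genes, −2.73 for stress keratins, 0.46 for MHC class II, 0.31 for Langerhans cell genes and −0.097 for glycolysis. They also gave −0.70 for MHC class I, −0.82 for NF-kB, −0.78 for the cAMP response, −0.84 for dissociation stress and 1.60 for mitochondrially encoded genes. Macrophage-like cells gave −2.695 for MHC class II, −1.39 for interferon-stimulated, 0.33 for NF-kB, 0.70 for glucocorticoid and −0.31 for dissociation genes, and cluster 2 gave 0.41 for MHC class II and −0.18 for NF-kB.

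Scaling by the median ratio shifted all genes by 0.063 in CD8 T-like cells, −0.047 in keratinocytes, −0.030 in macrophage-like cells and 0.016 in cluster 2. Resolution 0.5 and the wild-type reference gave no value for CD8 T-like cells, averaging within clusters none for CD8 T-like cells and keratinocytes, and thinning none for lists not measured in each draw. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. Depth limited CD8 T-like cells, where 3 UMIs were worth a CPM of 15.9 in Gi-DREADD and 9.10 in control cells, against 0.295 and 0.311 in macrophage-like cells.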

Other observations

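The choice to describe the classes below, which fell under the size set for the report, was made after they had been seen, and no tests of explanations were run on them. Langerhans-like cells (106 Gi-DREADD and 136 control cells) had higher cell cycle genes in the Gi-DREADD library, with a median of 0.90 (0.47 to 1.26) and 5 of 5 measured members higher, including the proliferation marker Mki67 (1.88, 1.32 to 2.68; 30 of 87 Gi-DREADD UMIs in 1 cell) and the topoisomerase gene Top2a (4.94, 1.98 to 14.7; 14 of 25 in 1 cell). H2ac8, a histone gene and the highest by the fixed rule (10.3, 4.72 to 26.8), had 50 of 61 in 1 cell. Glycolysis and hypoxia genes were lower (−0.41, −0.56 to −0.20), with 6 of 12 members lower, among them the hexokinase gene Hk2 (0.663, 0.577 to 0.761) and the angiogenic factor Vegfa (0.641, 0.540 to 0.759). Dendritic cell maturation genes were lower too (−0.33, −0.51 to −0.04), with the costimulatory receptor gene Cd40 at 0.667 (0.550 to 0.806), and MHC class I genes had a median of −0.25 (−0.35 to −0.08). The cytokine gene Il23a was 5.42-fold lower (2.43 to 14.2), with 22 of its 45 control UMIs in 1 cell. Mitochondrially encoded genes had a median of 0.21 (0.17 to 0.29).

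γδ T-like cells (90 and 41 cells) held 53 UMIs of Il22, a cytokine that acts on epithelial cells, in 6 Gi-DREADD cells, 34 of them in 1 cell, against 0 in control. Il17f, a type 17 cytokine gene, stood at 1.61 (1.33 to 1.96) and Il17a at 1.01 (0.910 to 1.12), with 104 of 479 and 200 of 1133 Gi-DREADD UMIs in 1 cell. Genes of γδ T cells and DETC had a median of 0.94 (0.59 to 1.24), dissociation stress genes one of −0.32 (−0.48 to −0.16), with 9 of 21 members lower, and mitochondrially encoded genes one of 0.51 (0.42 to 0.60). A subcluster led by Trgv5 held 21 of the Gi-DREADD and 4 of the control γδ T-like cells. Ccl4 had 2 Gi-DREADD and 61 control UMIs, 59 of the latter in 1 cell. In CD4 T-like cells (136 and 193 cells), dissociation stress genes were lower (−0.35, −0.50 to −0.29, 13 of 22 members lower and 1 higher). Cytotoxicity and effector cytokine genes had a median of −0.32 (−0.46 to 0.05), with Ifng (0.526, 0.399 to 0.688; 73 of 182 control UMIs in 1 cell) and Il2 (0.513, 0.278 to 0.910) lower and Ccl4 (2.55, 1.34 to 5.07; 23 of 32 Gi-DREADD UMIs in 1 cell) and Ccl5 (1.45, 1.13 to 1.85) higher among 11 members. In the same cells the enkephalin precursor gene Penk was 18.2-fold lower (9.02 to 42.8), with 149 of 174 control UMIs in 1 cell. Mitochondrially encoded genes had a median of 0.36 (0.29 to 0.42) there.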
